A study of Mus musculus with 24 samples.

How the data were processed

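Transcripts of epithelial cells isolated from the distal ileum were counted with the NanoString nCounter assay, in which colour-coded probe pairs bind RNA directly and are counted without amplification. Each of 12 mice, 21 days old, was measured on 2 panels of predefined targets, to which the submitters added 30 custom targets per panel, per the series' design text. The mice carried a constitutive loss of Ptpn2, a tyrosine phosphatase, on both alleles (KO, 5 mice) or on 1 allele (HET, 4 mice), or were wild type (WT, 3 mice). Replicates are separate mice, numbered by the litter named in the labels, and KO replicates 4a and 4b come from the same litter. WT replicate 2 was the only male. Both panels of a mouse were treated as 1 replicate. The series' design text names a cancer pathway and an autoimmune panel, while the labels give code set names only. From their targets, the cancer pathway panel is called panel A here and the autoimmune panel B.

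The values of each panel are the authors' deposited normalized signal, and the panels were normalized separately and then consolidated by the MultiRLF function of nSolver Analysis Software 4.0, per the series' design text. The settings used in that software are not given in the sources used here, and the following was found from the deposited signal values. In each library, targets at or under the geometric mean of the 8 negative controls sit at that geometric mean, and every other target is a whole count times 1 factor for the library. Within a tolerance of 0.02 units, at least 99.6% of the values above the floor on panel A and 98.9% on panel B came out whole. The floor is not multiplied by the factor, so a target just above the floor of a library with a large factor takes a value well above the floor. The share of targets at the floor was 17.3% to 33.3% on panel A and 11.4% to 24.7% on panel B. Because of these values at a floor, a count model was not used. The authors' deposited comparison tables hold a log2 fold change with its standard error, a p-value and an FDR per target, per the file headers, for KO and for HET against WT. The software behind them is not given in the sources used here.

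The analysis had been planned on the consolidated table of both panels. Its 12 value columns are only numbered and match no label, so they were not used, and the tables of each panel were used instead. A gene measured once by each panel was averaged on the log2 scale (161 of 179 shared names), and the 18 shared names with probes that differ were kept as separate targets, which gave 1431 targets. Of 1413 names, 1393 were matched to current mouse symbols by transcript accession in the reference gene table (GRCm38.p6) and 18 by symbol only, 2 stayed unmatched and keep the name in the files, and 58 symbols were updated. Probes of the defensin and H2 families can bind closely related transcripts, so values of single members of these families are uncertain. Ptpn2 itself was not analysed here, so the targeted gene gave no check of the genotype labels.

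Values were taken to log2(value + 1), and the 970 targets with a mean of at least 20 over the 12 mice were tested. The added 1 makes the log2 change of genes with low values smaller. In libraries with a large factor the change of such genes may instead be larger, since counts just above the floor are multiplied up. Genotypes were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, in 1 fit over all 12 mice, and p-values were adjusted by the Benjamini-Hochberg method over all tested targets, with a threshold of 0.05. All adjusted p-values of single genes come from this limma fit unless the authors' deposited table is named. The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. There were 24 lists, of which 17 had at least 5 tested members and were compared with all other tested targets by limma's camera with a preset correlation of 0.01, adjusted over the lists. Camera was also run with an estimated correlation. The interferon list shares members with the JAK-STAT list, such as Socs1, and with the MHC class I list, such as Psmb8.

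The rule named the 10 largest rises and the 10 largest falls among genes that passed for KO against WT, up to 4 members with the smallest p of each list, and the 5 largest rises and falls that passed for the other comparisons, or the 3 genes with the smallest p where none passed. Some genes that met the rule are not reported here by name, while counts and lists include them. Genes outside this rule are said to have been chosen after their values were seen.

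The depth of each library was taken as the sum of the whole counts recovered from the normalized values. Panel A libraries held 462193 to 572974 counts. On panel B, the libraries of KO replicates 2, 3, 4a and 4b held 97276 to 251886 counts and the other 8 held 389029 to 751742. A background limit per library was set at the mean plus 2 SD of its negative controls, times its factor.

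Litters pair the mice, since the labels name a shared littermate group. Deviations from the group means over the tested genes were correlated between mice of unlike genotype, which leaves out the pair of KO replicates 4a and 4b. The median correlation was 0.21 in 12 littermate pairs (range -0.2 to 0.65) and -0.08 in 35 other pairs. Pairs of litter 1 had 0.55 to 0.65 and pairs of litter 4 had -0.2 to 0.15. The consensus correlation within litters was 0.28. Alternatives planned in advance were a pseudocount of 10, no filter or a mean of at least 50, median centring, quantile normalization, litter as a fixed or a random block (with statmod 1.5.0), a fit of only the 2 genotypes compared, eBayes with trend and robust estimation, exact permutation tests, each panel alone, each mouse left out, and the authors' deposited tables. Further alternatives were added after the data were seen. One set all values of a panel under its highest background limit to that limit (22.6 on panel A and 192.6 on panel B). That alternative removes differences between values under the limit, so a call lost with it does not argue against a change. Another left out panel B of KO replicates 2, 3, 4a and 4b, so that genes measured only on panel B rested on KO replicate 1, assumed to vary like the mice of the other groups. The same was also fitted with litter as a fixed block.

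The procedure was tested on simulated data with the means and spread of the real values. The simulated noise was independent between genes and mice, with the same spread in all genotypes. It held no litter effect, floor or library of low depth, so the following shares hold only without them. For KO against WT it recovered 61% of 100 genes changed by 1 on the log2 scale and 88% of 100 changed by 2, and called 5 unchanged genes. For HET against WT it recovered 64% and 91%, with 9 unchanged genes called, and for KO against HET 68% and 90%, with 13. With no simulated change it called 0 of 970 genes in each comparison. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.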

Results

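Targeted transcript levels were measured in isolated ileal epithelial cells of 5 KO, 4 HET and 3 WT mice, 21 days old, on panels A and B. The comparisons ask how gene expression of the ileal epithelium differs without Ptpn2, a phosphatase that acts on JAK and STAT proteins, and whether the loss of 1 allele is enough for a difference. KO mice of this line are normal at birth and die young, per the series' design text.

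Library depth was similar across genotypes on panel A and differed on panel B. Panel A libraries held 474298 to 572974 counts in WT mice, 505245 to 560258 in HET mice and 462193 to 531270 in KO mice. On panel B, 4 of 5 KO libraries held 97276 to 251886 counts, against 389029 to 751742 in the other 8 libraries. Their counts had been multiplied by factors of 2.271 to 8.494 in the normalization, against 0.573 to 1.091 elsewhere, and their background limits lay at 57.5 to 192.6 normalized units, against 7.7 to 31.0. In these 4 libraries the positive control POS_A had values of 118 to 870, against 2248 to 9037 in the other 8. In KO replicate 2 it lay below the positive control POS_D (187). The cause of these low values was not tested and cannot be parted from the genotype in these mice. The same 4 mice had panel A background limits of 16.6 to 22.3 and POS_A values of 14694 to 19334 there. For many lists and some single genes, values of panel B in KO mice are therefore given below also without these 4 libraries. This comparison was chosen after the data were seen, and in it panel B rests on KO replicate 1 alone.

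**Figure D1:**
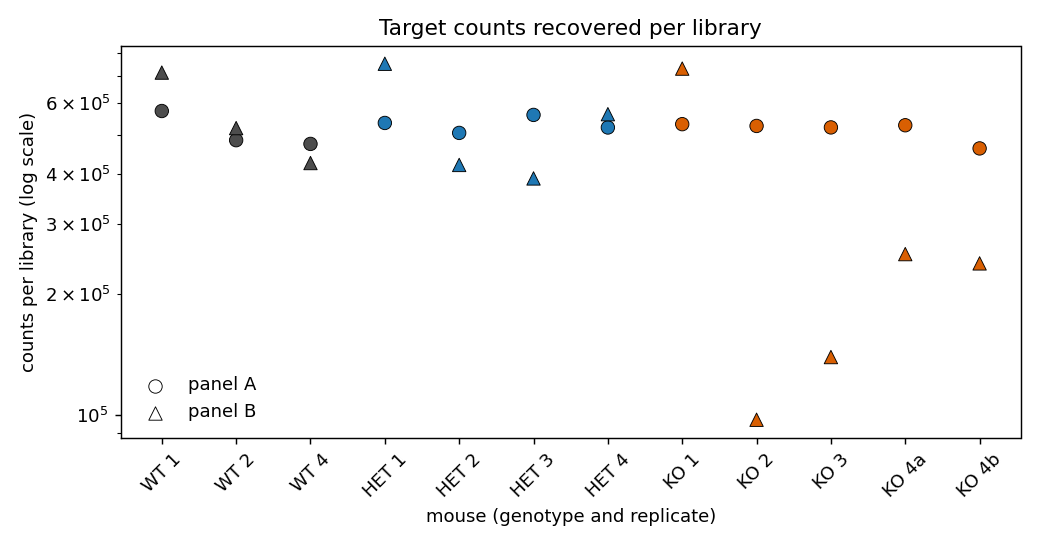
Counts recovered per library (vertical axis, log scale) for each mouse (horizontal axis), with circles for panel A and triangles for panel B and the genotype as colour (WT grey, HET blue, KO orange). The triangles of KO replicates 2, 3, 4a and 4b lie at 97276 to 251886 counts, below the other 8 libraries of panel B at 389029 to 751742.

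Interferon-stimulated genes rose together in KO mice compared with WT mice. Of 34 measured members, 25 rose, 1 fell and 8 did not pass, with a median log2 change of 2.35. The antiviral membrane protein gene Ifitm3 rose by 3.73 (SE 0.27, adjusted p = 2.68e-06), from 257.1 ± 104.2 normalized units (SD, n = 3) in WT mice to 3318 ± 682 (SD, n = 5) in KO mice. The guanylate-binding protein gene Gbp2 rose by 5.22 (SE 0.31, adjusted p = 4.84e-07), the JAK-STAT inhibitor Socs1 by 3.54 (SE 0.32, adjusted p = 1.08e-05) and Cxcl9, a chemokine that attracts T cells, by 3.72 (SE 0.17, adjusted p = 5.76e-08), each in 5 of 5 KO mice. The sizes for Gbp2 and Cxcl9 are uncertain, since their WT values lay at or near background. Gbp2 changed by 1.36 with the common background limit, and Cxcl9 was not tested with it and lay under the limits of the libraries themselves in KO replicates 2 and 3. Ifi27 was the member that fell, by 1.90 (SE 0.28, adjusted p = 0.000521, lower in 5 of 5 KO mice). Adjusted over the list alone, 30 members rose and 1 fell. The list differed from the other genes by camera (adjusted p = 6.93e-19, and adjusted p = 0.00685 with an estimated correlation, which became 0.0859 with litter as a block). Only 2 members lay on panel A, and both rose there. Without the 4 panel B libraries of low depth, 20 members rose and the median was 2.20, and with the common background limit 19 of 29 rose and the median was 1.43.

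Genes of antigen presentation rose in KO mice as well. Of 9 MHC class II genes, 8 rose, with a median of 4.47, and the same number passed when adjusted over the list alone. H2-Aa, the alpha chain of a class II molecule, rose by 5.85 (SE 0.47, adjusted p = 4.84e-06), from 314.1 ± 189.8 (SD, n = 3) to 15560 ± 842 (SD, n = 5) normalized units. H2-Eb1 rose by 5.35 (SE 0.40, adjusted p = 2.68e-06) and the peptide loading factors H2-DMa by 3.50 (SE 0.28, adjusted p = 4.84e-06) and H2-DMb1 by 5.28 (SE 0.42, adjusted p = 4.72e-06). Each of the 4 was higher in 5 of 5 KO mice than the WT mean. The class II list had a camera adjusted p of 6.02e-10, with adjusted p = 0.0397 with an estimated correlation and 0.118 with that and litter as a block. Its members were measured on panel B only, and without the 4 libraries of low depth 7 of 9 rose, with a median of 4.15.

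Of 10 MHC class I genes, 8 rose, with a median of 1.50, and 8 also passed when adjusted over the list alone. B2m, the light chain of class I molecules and measured on panel A, rose by 1.65 (SE 0.26, adjusted p = 0.000875), from 33430 ± 1379 (SD, n = 3) to 107400 ± 25500 (SD, n = 5) normalized units. The immunoproteasome subunits Psmb8 and Psmb9 rose by 2.97 (SE 0.34, adjusted p = 9.34e-05) and 2.56 (SE 0.29, adjusted p = 8.12e-05), and the heavy chain gene H2-D1 by 1.34 (SE 0.17, adjusted p = 0.000162), each in 5 of 5 KO mice. Camera gave an adjusted p of 1.49e-05 for the list, and the call was lost with an estimated correlation (adjusted p = 0.0823 with an estimated correlation). With the 4 libraries of low depth left out, 4 members rose, with a median of 1.12. Psmb9 changed by 1.43 with the common background limit, and with quantile normalization B2m changed by 1.09 and H2-D1 by 0.62.

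**Figure D2:**
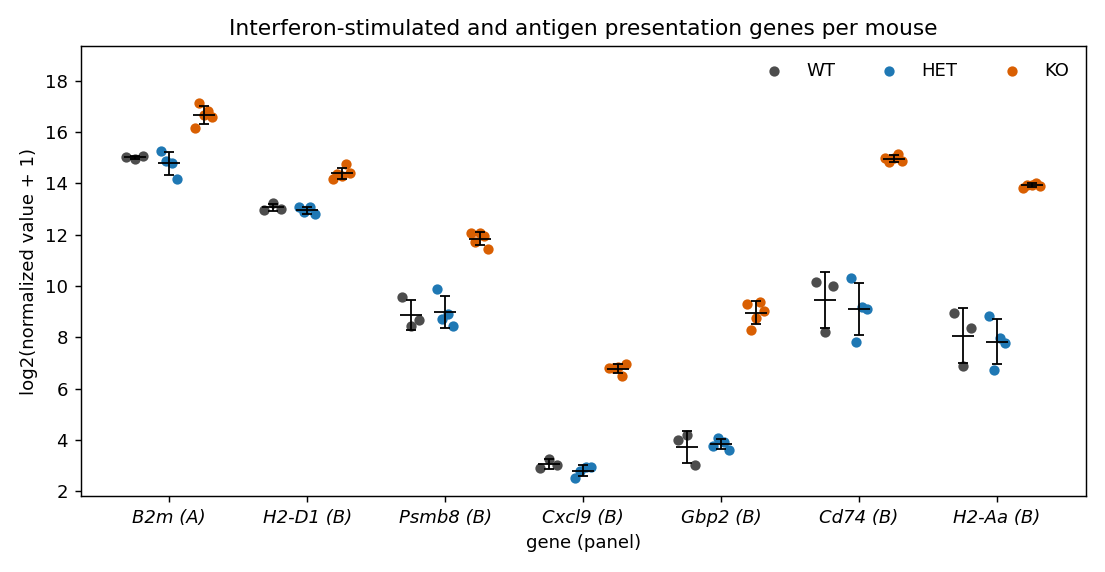
Log2(normalized value + 1) of 7 interferon-stimulated and antigen presentation genes per mouse (points), with the mean and SD of each genotype (black), for WT (grey, n = 3), HET (blue, n = 4) and KO (orange, n = 5), and with the panel of each gene in brackets. All 5 KO mice lie above the WT mean for each gene shown, with log2 changes from 1.34 for H2-D1 to 5.85 for H2-Aa.

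Among components of JAK-STAT signalling, 3 of 25 rose, 2 fell and 20 did not pass, and adjusted over the list alone 5 rose and 3 fell. Socs1 rose by the 3.54 given above, with 3.30 on panel A and 3.79 on panel B. Stat2 rose by 0.97 (SE 0.24, adjusted p = 0.0211) and Stat5b fell by 0.64 (SE 0.16, adjusted p = 0.0211). Stat5b lost the call without the 4 panel B libraries of low depth (-0.81), and Stat2 with median centring (0.57) and quantile normalization (0.73). The size of the fall of Stat5b is uncertain, since it was measured on panel B only. Over 113 genes measured by both panels, the KO change was lower on panel B by a median of 0.32. Both lost the call without WT replicate 4 (log2 0.89 and -0.54), Stat2 also without WT replicate 1 (0.88) and Stat5b also without WT replicate 2 (-0.67). The list was not called over both panels (camera adjusted p = 0.419, and 0.785 with an estimated correlation). On panel A alone it was called higher (camera adjusted p = 0.00219), with 14 members, a median of 0.45, 2 higher and 0 lower. The estimated correlation was not tried on panel A alone.

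Markers of Paneth cells, the secretory cells of the crypt base that release antimicrobial peptides, were lower in KO mice. All 6 measured members lay on panel A, which had similar depth in all genotypes. A member that did not pass, Dll4, was also measured on panel B and averaged (-0.09 on panel A and -0.26 on panel B). Of these, 3 fell and 3 did not pass, and 4 fell when adjusted over the list alone, with a median of -1.03. Lysozyme (Lyz1) fell by 1.94 (SE 0.32, adjusted p = 0.00125), from 24990 ± 6303 (SD, n = 3) to 6530 ± 1691 (SD, n = 5) normalized units. The phospholipase Pla2g2a fell by 1.61 (SE 0.21, adjusted p = 0.000198) and the alpha-defensin Defa5 by 1.46 (SE 0.33, adjusted p = 0.0114). The transcription factor Sox9 had a change of -0.60 (SE 0.22, adjusted p = 0.0808). A further defensin, DEFA6 as named in the files and outside the list, fell by 1.74 (SE 0.28, adjusted p = 0.00105). All 5 of these genes were lower than the WT mean in 5 of 5 KO mice. Defa5 lost the call without WT replicate 4 (log2 -1.33), and changed by -0.96 with quantile normalization. Camera gave an adjusted p of 0.00451 for the list, and the call was lost with an estimated correlation (adjusted p = 0.206 with an estimated correlation).

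Of 7 stem cell markers, 0 passed over all genes by limma and 0 when adjusted over the list alone, with a median of -0.53 (camera adjusted p = 0.0815). Olfm4 changed with a log2 value of -0.83 (SE 0.35, adjusted p = 0.119). Of 4 goblet cell markers, Atoh1, a transcription factor of secretory cells, fell by 0.64 (SE 0.18, adjusted p = 0.0344), while Muc2, the main gel-forming mucin, had a change of -0.97 (SE 0.41, adjusted p = 0.119) and 3 members fell when adjusted over the list alone. With median centring 3 of the 4 fell, Muc2 among them (-0.91). Atoh1 lost the call without WT replicate 2 (-0.55), WT replicate 4 (-0.60), HET replicate 2 or 3 (-0.64 each), KO replicate 3 (-0.60) or KO replicate 4a (-0.65). Of 2 tuft cell markers, Dclk1 fell by 1.23 (SE 0.30, adjusted p = 0.0172), with 1 member passing when adjusted over the list alone, and lost the call without WT replicate 4 (-1.08) and with the common background limit (-0.28). The enteroendocrine marker Chga (-0.43, SE 0.19, adjusted p = 0.124) passed only when adjusted over its list of 1 tested member. Neither of the 2 enterocyte markers, Alpi (0.36, SE 0.31, adjusted p = 0.431) and villin (0.34, SE 0.23, adjusted p = 0.320), nor any of 3 junction genes passed, and 0 of them passed when adjusted over the lists alone. With quantile normalization villin (0.75) and Alpi (0.67) passed, and with median centring the junction gene Cdh1 (0.67) did.

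**Figure D3:**
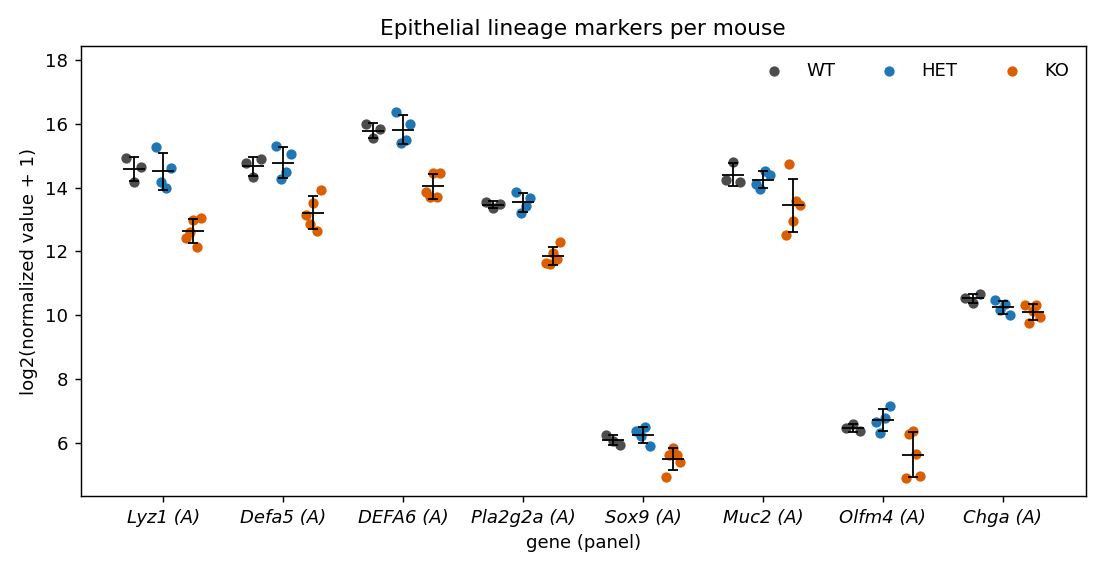
Log2(normalized value + 1) of 8 epithelial lineage markers of panel A per mouse (points), with the mean and SD of each genotype (black), for WT (grey, n = 3), HET (blue, n = 4) and KO (orange, n = 5). Lyz1, Defa5, DEFA6 and Pla2g2a lie lower in all 5 KO mice than the WT mean, by 1.46 to 1.94 in the mean, while Sox9, Muc2, Olfm4 and Chga did not pass the test.

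Most immune cell markers lay on panel B, which had low depth in 4 of 5 KO mice. Of 16 markers of T cells and intraepithelial lymphocytes, 8 rose, with a median of 2.19, and 12 rose when adjusted over the list alone. The granzymes Gzma and Gzmb, proteases of cytotoxic lymphocytes, rose by 3.34 (SE 0.53, adjusted p = 0.000967) and 2.43 (SE 0.35, adjusted p = 0.000521), the receptor chain Il2rb by 2.00 (SE 0.31, adjusted p = 0.000814) and the transcription factor Eomes by 3.41 (SE 0.85, adjusted p = 0.0211), each in 5 of 5 KO mice. On panel A alone, Gzmb changed by 2.44 and Il2rb by 1.73, and both rose there. The list's camera adjusted p was 2.5e-05, with adjusted p = 0.335 with an estimated correlation. Without the 4 panel B libraries of low depth, 3 members rose, the median was 0.50 and the call of Eomes was lost (0.92). With the common background limit 2 of 10 rose, the median was 0.82, Gzma changed by 1.88 and Gzmb by 0.80, and Eomes (0.92) and Il2rb (0.60) lost their calls. With the 4 libraries left out and litter as a block, the median was 1.08 and Eomes changed by 1.94, not called. Eomes also lost it without WT replicate 1 (3.08) or WT replicate 2 (3.38).

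Of 12 inflammatory cytokines and chemokines, 2 rose, with a median of 1.53, and 4 rose when adjusted over the list alone. Ccl5 rose by 2.27 (SE 0.40, adjusted p = 0.00215) and Tnfsf10, also called TRAIL, by 1.45 (SE 0.30, adjusted p = 0.00700). Ccl5 was not called with quantile normalization (1.54). With the common background limit it changed by 0.09 and was not called, but nearly all its values lay under that limit, so a rise could hardly show there. Of 9 myeloid markers, Ly6c1 rose by 5.37 (SE 0.43, adjusted p = 4.84e-06) and the other 8 did not pass, with 1 rising when adjusted over the list alone and a median of 1.39. Of 7 B and plasma cell markers, 0 passed by limma over all genes, and 3 rose when adjusted over the list alone, with a median of 1.46. Tnfrsf17 had a value of 2.81 (SE 0.91, adjusted p = 0.0568), higher in 4 of 5 KO mice. It was called with litter as a block (2.52), median centring (2.41) and quantile normalization (2.26), and its value was 0.56 with the common background limit and -0.19 without the 4 libraries. Camera called the 3 lists higher, with adjusted p of 0.0183, 0.0411 and 0.0317, and no call held with an estimated correlation (adjusted p = 0.421, 0.206 and 0.619 with an estimated correlation). Without the 4 panel B libraries of low depth the medians were -0.12, -0.31 and -0.27, with KO replicate 1 set against WT mice of all litters. With these left out and litter as a block they were -0.06, 0.28 and -0.05, so the direction stays open. None of 3 markers of mast cells, basophils and eosinophils passed, and 0 passed when adjusted over the list alone. With quantile normalization the eosinophil marker Siglecf was called lower.

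Of 4 antimicrobial and host defence genes, the bacterial sensor Nod2 rose by 2.15 (SE 0.53, adjusted p = 0.0204), and 3 rose when adjusted over the list alone. Its call was lost without the 4 panel B libraries of low depth (0.62) and without WT replicate 1 (1.83) or WT replicate 2 (2.01). The size of the rise of Nod2 is uncertain, since its values lay under the background limits of these 4 libraries, and it was not tested with the common background limit. Of 9 stromal and vascular markers, 0 passed by limma, with 2 lower when adjusted over the list alone, a median of -0.77 and a camera adjusted p of 0.299. The probe of Thbs1 on panel A had a value of -0.77 (SE 0.25, adjusted p = 0.0554) and that on panel B of -1.58 (SE 0.51, adjusted p = 0.0571).

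Of 8 genes of autophagy and the lysosome, 3 fell, with a median of -0.50, and 4 fell when adjusted over the list alone. The lysosomal membrane protein gene Lamp1 fell by 1.14 (SE 0.19, adjusted p = 0.00137), the autophagy receptor Sqstm1 by 0.85 (SE 0.24, adjusted p = 0.0339) and Becn1 by 0.59 (SE 0.16, adjusted p = 0.0271), each in 5 of 5 KO mice. The camera adjusted p was 0.00863, with adjusted p = 0.0992 with an estimated correlation. Without the 4 panel B libraries of low depth 0 members passed by limma and the median was -0.41, while with median centring 6 fell and the median was -0.90. Median centring also moved the median change of all panel B genes from 0.20 to -0.20, so it deepens falls there. On panel A alone 2 members were tested, with a median of -0.08. Over 113 genes measured by both panels the KO change was lower on panel B by a median of 0.32, so the fall of this list is uncertain. Sqstm1 lost the call without WT replicate 2 (-0.57), WT replicate 4 (-0.90) or KO replicate 3 (-0.81), and Becn1 without any of the 3 WT mice (-0.62 to -0.54) or KO replicate 3 (-0.56).

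Cell death genes moved in both directions, with 5 of 26 higher, 2 lower and 19 not passing, and 10 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.554). The necroptosis kinase gene Ripk3 rose by 2.06 (SE 0.26, adjusted p = 0.000165), in 5 of 5 KO mice. Of 33 cell cycle genes, 3 rose and 30 did not pass, and 3 rose when adjusted over the list alone, with a median of 0.07 (camera adjusted p = 0.779). Ccne1 rose by 1.14 (SE 0.21, adjusted p = 0.00270) and Ccnd1 by 1.13 (SE 0.25, adjusted p = 0.00968). Ccnd1 lost the call without WT replicate 2 (0.87).

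Of 19 genes of the Wnt and Notch pathways, the secreted Wnt antagonist Sfrp1 rose by 2.72 (SE 0.23, adjusted p = 7.56e-06, higher in 5 of 5 KO mice) and Atoh1 fell as given above. The other 17 did not pass, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.274). Of 32 NF-kB pathway genes, the adaptor gene Myd88 rose by 0.93 (SE 0.27, adjusted p = 0.0367), Irak1 fell by 0.69 (SE 0.16, adjusted p = 0.0150) and Malt1 by 1.06 (SE 0.27, adjusted p = 0.0217), with 2 lower when adjusted over the list alone. The list was not called (camera adjusted p = 0.274, and 0.743 with an estimated correlation). With median centring it was called lower, with a median of -0.37, 2 higher and 5 lower, and the estimated correlation was not tried there. Without the 4 panel B libraries of low depth Irak1 (-0.66) and Malt1 (-1.34) lost their calls, as they did without WT replicate 2 (-0.66 and -0.80). With the common background limit they changed by 0.00 and -0.02 and were not called. Nearly all their WT and KO values lay under that limit, so a fall could not show there. Irak1 also lost its call without WT replicate 1 (-0.68), and Myd88 did so in 7 of the 12 fits that left out a mouse (0.80 to 1.05). The sizes of the falls of Irak1 and Malt1 are uncertain, since both were measured on panel B only. Over 113 shared genes the KO change was lower there than on panel A by a median of 0.32. Of 8 genes of iron transport and storage, the ferric reductase gene Cybrd1 fell by 2.31 (SE 0.39, adjusted p = 0.00156), and 1 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.419). The size of the fall of Cybrd1 is uncertain, since its values lay under the background limit in 5 of 5 KO libraries, and in 4 of them that limit lay above the WT mean. It was not tested with the common background limit, and it changed by -2.25 without the 4 libraries.

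By fitted value, the largest rises in KO mice were those of Ifi44 (6.24, SE 0.85, adjusted p = 0.000329) and Ifi44l (6.05, SE 0.28, adjusted p = 5.76e-08), followed by H2-Aa, the invariant chain gene Cd74 (5.52, SE 0.52, adjusted p = 1.74e-05), Ly6c1, H2-Eb1, the nucleic acid sensor Zbp1 (5.30, SE 0.48, adjusted p = 1.12e-05), H2-DMb1, Gbp2 and arginase 1 (Arg1, 4.67, SE 1.03, adjusted p = 0.00995). The order depends on background: with the common background limit Ifi44 changed by 3.45, Ifi44l by 1.57, Ly6c1 by 2.91, H2-DMb1 by 2.94 and Gbp2 by 1.36, below H2-Aa (5.62), Cd74 (5.52), Zbp1 (4.83) and H2-Eb1 (4.73). The size for Ifi44 also depends on the litter. Its log2 value was 6.717 in WT replicate 1 and 7.616 in HET replicate 1, both of litter 1. In the other WT and HET mice it was 3.265 to 4.855, and in KO mice 10.247 to 11.653. The call of Arg1 was lost without the 4 panel B libraries of low depth (1.52) and with the common background limit (0.95). Beside Cybrd1, Lyz1, Ifi27, DEFA6 and Pla2g2a, the largest falls were those of Maml3 (-2.28, SE 0.58, adjusted p = 0.0217), Bmp4 (-2.21, SE 0.51, adjusted p = 0.0142), Rps6ka5 (-1.98, SE 0.19, adjusted p = 1.64e-05), Plcg1 (-1.91, SE 0.58, adjusted p = 0.0468) and Fgfr3 (-1.79, SE 0.46, adjusted p = 0.0222). Rps6ka5 changed by -0.87 on panel A and -3.09 on panel B, by -0.87 without the 4 panel B libraries of low depth and by -0.43 with the common background limit. Calls were lost without WT replicates 2 or 4 for Bmp4 (-1.80 and -1.98, and -1.59 with the common background limit) and Fgfr3 (-1.84 and -1.47) and without any 1 of the WT mice for Maml3 (-2.37 to -2.19), which like Plcg1 was not tested with the common background limit. The values of Maml3 and Plcg1 lay under the background limits of the 4 KO libraries of low depth, so the sizes of their falls are uncertain. Plcg1 lost its call in 9 of the 12 fits that left out a mouse (-2.05 to -1.57), and was not called without the 4 panel B libraries of low depth (adjusted p = 0.405, and -0.90 with adjusted p = 0.196 with litter as a block there).

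In all, 154 of 970 genes differed between KO and WT mice by limma, 97 higher and 57 lower, of which 34 lay on panel A only, 20 on both panels and 100 on panel B only. At unadjusted p under 0.05 there were 336. On panel A alone 44 of 494 genes passed, 26 higher and 18 lower. With panel B of the 4 mice left out 94 passed, 62 higher and 32 lower, and 85 of the 154 remained. With median centring 256 passed, 117 higher and 139 lower, so that the share of higher calls moved from 63% to 45.7%, and the median change of panel B genes moved from 0.20 to -0.20. The count was 97, 87 and 87 without WT replicates 1, 2 and 4. Without KO replicate 1 it was 302, with 218 higher and 84 lower. All KO libraries of panel B left in that fit were of low depth, so depth and genotype coincide there. In the authors' deposited table, 73 of 1395 targets had an FDR under 0.05, 51 higher and 22 lower, and 151 of 151 calls that could be compared had the same sign there, 65 of them with an FDR under 0.05. At their p under 0.05 the balance was the other way, with 245 higher and 279 lower.

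HET and WT mice were compared to ask whether the loss of 1 allele changed expression. None of 970 genes passed by limma, and 2 had an unadjusted p under 0.05. Dclk1, a marker of tuft cells, was 1.12 higher in HET mice (SE 0.31, unadjusted limma p = 0.0038, higher in 4 of 4 HET mice). It did not pass over all genes, and passed when adjusted over the 2 tested tuft cell markers alone. Dusp8 had a change of 0.57 (SE 0.22) and the eosinophil marker Siglecf of 1.12 (SE 0.53), both higher in 4 of 4 HET mice and not passing. The interferon-stimulated list had a median of -0.02, MHC class II of -0.15, MHC class I of -0.11 and Paneth cell markers of 0.12, with 0 members passing by limma in each, also when adjusted over the list alone. In the authors' deposited table, 0 of 1397 targets had an FDR under 0.05 and 23 had a p under 0.05.

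Camera called 2 lists for HET against WT. Cell cycle genes had a median of 0.09 and a camera adjusted p of 0.0152, and genes of autophagy and the lysosome a median of -0.13 and the same adjusted p. Neither call held with an estimated correlation (adjusted p = 0.916 and 0.312 with an estimated correlation), and with litter as a block the autophagy list had an adjusted p of 0.0609 and the cell cycle list of 0.000728. The other 15 tested lists had adjusted p of 0.332 to 0.988. The cell cycle call was lost without WT replicate 2 (camera adjusted p = 0.740), WT replicate 4 (0.232), HET replicate 1 (0.0656) or HET replicate 4 (0.368). The autophagy call was lost without WT replicate 2 (camera adjusted p = 0.279), HET replicate 1 (0.0656) or HET replicate 4 (0.368).

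KO and HET mice differed in 191 of 970 genes by limma, 117 higher and 74 lower in KO, with 357 at an unadjusted p under 0.05. By fitted value, the largest rises were those of H2-Aa (6.09, SE 0.44, adjusted p = 1.48e-06), Ifi44l (6.02, SE 0.26, adjusted p = 2.36e-08), Cd74 (5.86, SE 0.48, adjusted p = 4.92e-06), Ifi44 (5.80, SE 0.78, adjusted p = 0.000252) and Ly6c1 (5.53, SE 0.40, adjusted p = 1.48e-06), each in 5 of 5 KO mice. Dclk1 fell by 2.35 (SE 0.27, adjusted p = 7.69e-05), Bmp4 by 2.31 (SE 0.47, adjusted p = 0.00549), the cytokine receptor gene Il18r1 by 2.23 (SE 0.54, adjusted p = 0.0139) and Maml3 by 2.13 (SE 0.53, adjusted p = 0.0164). With the common background limit Dclk1 changed by -1.40 and Bmp4 by -1.70, while Il18r1 and Maml3 were not tested, and their KO values lay under the limits of the 4 libraries of low depth. By the same limit Ifi44l (1.57), Ifi44 (3.45) and Ly6c1 (2.91) lay below H2-Eb1 (4.73) and Zbp1 (4.68), so the order of the rises depends on background. Babam1, a housekeeping probe of panel B, fell by 3.13 (SE 0.96, adjusted p = 0.0405, lower in 4 of 5 KO mice) and had a value of 0.07 without the 4 panel B libraries of low depth. Of the interferon-stimulated list 28 of 34 rose and 1 fell (31 and 1 when adjusted over the list alone), 8 of 9 MHC class II genes rose (8), and 4 of 6 Paneth cell markers fell (4). With litter as a block the count was 301, 181 higher and 120 lower. On panel A alone 55 of 494 passed, 26 higher and 29 lower, and without the 4 panel B libraries of low depth 114 passed, 65 higher and 49 lower. With median centring 313 passed, 142 higher and 171 lower, and without HET replicate 4 the count was 120. Without KO replicate 1 it was 318, where all KO libraries of panel B left were of low depth.

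Genes measured by both panels gave a technical repeat of the same RNA. Across 113 shared genes with a mean of at least 20 on both panels, the KO minus WT log2 changes of the panels had a Pearson r of 0.80 and a Spearman rho of 0.62, with 77 of the same sign and a median absolute difference of 0.50. Genes are not independent replicates, and no test was made of this correlation. Among the shared genes, Socs1, Gzmb, Il2rb and Tnfsf10 rose on each panel when tested alone.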

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

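Of the tests in this part, those of splits of the mice over both panels were planned, and the splits on panel A alone and all tests of technical explanations were chosen after the results were seen.

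A library or gene value was picked out where 1 mouse lay far from the others of its group in Dixon's test, which was met in 8 of 212 groups of values (6 in KO mice and 2 in HET mice). Chance alone picks out about 1 in 20 groups. Among genes, on the log2 scale, Stat2 was 8.61 in KO replicate 2 (9.38 to 9.66 in the other KO mice) and the panel B probe of Thbs1 was 2.73 in KO replicate 3 (4.77 to 5.44). In HET replicate 4, Ctnnb1 was 13.0 (13.14 to 13.16 in the other HET mice) and Nod1 was 6.16 (5.1 to 5.23). On panel A, KO replicate 4b had a total of 462193 counts (521460 to 531270 in the other KO mice), and KO replicate 1 had 33.3% of targets at the floor (17.3% to 21.9%). On panel B, KO replicate 1 had a total of 731060 counts (97276 to 251886 in the other KO mice). Its positive control POS_A was 7060 there (118 to 870). These last values set KO replicate 1 beside the WT and HET libraries of panel B, and it is the other 4 KO libraries that were low.

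The gene counts were set against other splits of the same mice. For KO against WT, 2 of 56 splits gave as many genes as the real one (154, highest other 271). By this share, under the limit of 0.05 set in advance, chance was excluded. Another grouping of the same mice gave more genes, so the count alone does not tie the genes to the genotype. The shares were not adjusted for the number of split tests. The split with 271 genes set KO replicates 2, 3 and 4a against the 3 WT mice with KO replicates 1 and 4b. It follows the factors of panel B (2.621 to 8.494 in these 3 mice) but not the counts (251886 in KO replicate 4a and 238812 in 4b), and it was also the highest other split on panel A alone, so what it follows stays open. Among the 11 splits that part as many littermate pairs as the real one, the highest other count was 0. On panel A alone, 1 of 56 splits gave as many (the real one, 44, highest other 23), and chance was excluded. For the lists, 6 of 56 splits gave as many as the real 9 (highest other 12), and chance was not excluded. For KO against HET, 1 of 100 splits gave as many genes (the real one, 191, highest other 89). On panel A alone it was 1 of 100 (55, highest other 30, with KO replicate 1 set among the HET mice). The other splits were drawn at random from all possible ones, separately for each test, and splits not drawn were not tried. Chance was excluded for both by the share of the drawn splits only. For lists of HET against WT, 26 of 35 splits gave as many as the real 2 (highest other 5), and chance was not excluded. For its genes the split test decides nothing, since a real count of 0 by limma (2 at unadjusted p under 0.05) is met by all 35 of 35 splits whatever the data (highest other 0).

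Of the immune cell and cytokine genes 11 rose in KO mice, and 4 of 5 KO libraries of panel B were low in counts that had been multiplied up. Low counts multiplied up may raise genes near background on panel B: of 37 shared genes under the panel A background limit in every mouse, 37.8% lay over 1 log2 above WT on panel B in the 4 KO mice (0% on panel A and 0% in KO replicate 1), a test chosen after the next 2 had been seen. Those 2 went against it: of 13 shared genes that rose on panel B alone, 1 lay under the panel A background limit (Cxcl1, -0.15 on panel A and 3.54 on panel B), and of the other 12, 8 also rose on panel A alone. Of the immune and cytokine genes, 6 of 11 stayed called without the 4 libraries, which argues against it as the whole cause for the group, while 4 of 11 stayed called with the common background limit, where Ccl5 (0.09) and Il2rb (0.60) also lost their calls. For the 5 whose calls ended (Cd28, Cd3d, Cd3e, Cd3g and Eomes), the median fell from 3.40 (SD 0.81) to 0.77 (SD 0.35) with 1 KO mouse left and litter not taken into account, and a rise and multiplied background cannot be told apart, since they were picked by the ended call. RNA of more immune cells in the KO isolates stays open: 2 of 3 T cell, B cell and myeloid members measured on panel A rose there (Gzmb and Il2rb), while which of these genes the epithelium itself expresses was not assessed, so the 2 sources cannot be told apart.

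Interferon-stimulated and MHC genes rose in KO mice. Low counts multiplied up are argued against as the whole cause, since 31 of 39 called members stayed called with the common background limit (35 tested) and 27 without the 4 libraries. RNA of immune cells and a rise within epithelial cells cannot be told apart for these genes: 3 of 16 T cell, B cell and myeloid members rose with the common background limit (Gzma, Gzmb and Ly6c1), and the labels describe no sorting of the cells. A response of the epithelium to the loss of Ptpn2 stays among the open explanations, as untested.

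Of 6 Paneth cell markers, 3 fell in KO mice on panel A and 3 did not pass. The camera call of the list was lost with an estimated correlation (camera adjusted p = 0.206). Scaling of the panel by the authors is argued against, since the other 488 genes of panel A had a median change of -0.06, against -1.03 (SD 0.78) for the markers. By the rule set for it, cell cycle genes go against a lower share of crypt cells alone, with a median of 0.07 (SD 0.42). Stem cell markers had -0.53 (SD 0.22). The cell cycle median measures the crypt share only if expression per cell did not change. That was not tested, and 3 of the 33 cell cycle genes rose and 0 fell, so a lower share of crypt cells stays open. Fewer Paneth cells and lower expression per cell stay open, as untested.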

How the results depend on the processing

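The common background limit and the removal of 4 panel B libraries, without and with a litter block, were chosen after the results were seen. Panel B had low depth in 4 KO mice. For KO against WT (154 genes), counts were 126 to 206 with a pseudocount of 10, other filters, a fixed litter block and trend and robust estimation, and 113 with the common background limit. They were 256 with median centring, 254 with quantile normalization, 254 with litter as a random block, 88 with only the 2 genotypes compared, 44 on panel A alone (fewer genes tested), 94 without the 4 panel B libraries of KO replicates 2, 3, 4a and 4b (fewer samples), 0 by exact permutation (177 at unadjusted p under 0.05; 56 splits limit the p), and 524 by p and 73 by FDR in the authors' deposited table. Without 1 mouse at a time they were 87 to 302 (97, 87 and 87 without WT replicates 1, 2 and 4, and 302 without KO replicate 1). In the fit without KO replicate 1, all KO libraries of panel B were of low depth.

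For KO against HET (191 genes), counts were 313 with median centring, 301 with a fixed and 332 with a random litter block, 55 on panel A alone, 114 without the 4 libraries, 0 by exact permutation (283 at unadjusted p under 0.05) and 120 to 318 without 1 mouse at a time (120 without HET replicate 4, 318 without KO replicate 1). No authors' table was used for it. Of 97 named genes for KO against WT, the fixed litter block added calls for 10 and ended 0, and it changed no other call of a named gene. For HET against WT (0 by limma, 2 at unadjusted p under 0.05), counts were 0 without 1 mouse at a time and 23 by p in the authors' table. With only the 2 genotypes compared the count was 0 (13 at unadjusted p under 0.05).

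The number of lists called for KO against WT (9) was 5 without the 4 libraries (5 with a litter block there), 2 with an estimated correlation and 7 to 9 without 1 mouse at a time. The number for HET against WT (2) was 0 with median centring, 0 without the 4 libraries (1 with a litter block there), 0 with an estimated correlation, 1 with the litter block and 1 to 2 without 1 mouse at a time. These were other lists without WT replicate 2 (1), HET replicate 1 (2) or HET replicate 4 (1), where neither of the 2 calls remained. Medians turned to -0.12 for cytokines, -0.27 for B cell and -0.31 for myeloid markers without the 4 libraries (-0.06, -0.05 and 0.28 with a litter block there), as did Babam1 in KO against HET (0.07), and Siglecf in KO against WT turned to -0.96 with quantile normalization. The agreement of the panels was 0.60 over all 161 shared genes. Beyond the effects of fewer genes or mice, the cause was not tested. Alternatives on Ptpn2 itself and on the consolidated table were not run.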

Other observations

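All values in this part were chosen after they were seen. Ciita, the gene of the coactivator of MHC class II transcription, was higher by 2.95 in KO than in WT mice (SE 0.36, adjusted p = 0.000149 by limma, higher in 5 of 5 KO mice), from 18.6 ± 4.43 (SD, n = 3) to 151.2 ± 37.8 (SD, n = 5) normalized units. Its values lay near the background of panel B, and its change was 2.79 without the panel B libraries of KO replicates 2, 3, 4a and 4b. With the common background limit its change was 0.02, but that limit lay above its KO mean, so a rise could hardly show there.

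Between the panels, the change of shared genes in KO against WT was lower on panel B than on panel A by a median of 0.32 on the log2 scale over 113 genes, while in HET against WT the median difference was 0.01.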
